A study of Schizosaccharomyces pombe with 9 samples.

How the data were processed

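RNA of Schizosaccharomyces pombe was measured on 9 Affymetrix arrays, 3 for each of 3 strains. WT was the control strain SPQ-01, SD1 lacked rpl32-1 (rpl3201 in the current annotation) and SD2 lacked rpl32-2 (rpl3202). Per the labels, cells grew in YEPD medium at 30 °C to an OD600 of 5.0 and were called log phase. Total RNA came from a Trizol extraction, and 500 ng of it was turned into biotinylated cRNA with the 3' IVT express kit.

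The deposited values were log2 expression values, 1 per probe set and array, which the authors made with RMA and Partek per the labels' tool list. No versions or settings were given for either tool, and background correction and joint normalization of the arrays were not stated. Exact equal values showed how the arrays had been summarised. Arrays numbered 1 shared 3934 to 4218 equal values per pair, arrays numbered 2 shared 74 to 80, and arrays numbered 3 shared 168 to 353. The 27 pairs of arrays with different numbers shared 0 to 4. These counts were over all probe sets. Among the S. pombe probe sets they were 238 to 412, 2 to 9 and 10 to 12, and 0 to 1 for different numbers. The 3 arrays of each number therefore looked processed together and apart from the rest, and each such set held 1 array of every strain. The number was treated as a processing set, and medians of the called gene lists are given within each number.

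The table held 10928 probe sets for 2 yeasts. The probe table named 5538 of them. Of these, 2937 belonged to S. pombe, 2917 with 1 gene symbol and 20 with several, and 2601 to S. cerevisiae. A further 5177 probe sets carried no name here, 166 were Affymetrix controls and 47 were reporter probe sets. Symbols were updated by gene number to the annotation of assembly ASM294v3, with 4 probe sets matched by symbol instead. The 2917 probe sets with 1 symbol covered 2899 genes. No gene was named from a probe set with several symbols.

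Arrays give no depth, so the number of arrays limits the precision. The 95th percentile of the S. cerevisiae probe sets served as a background yardstick and averaged 5.17 over the arrays. Between 97.6% and 98.9% of the S. pombe probe sets lay above it per array. A fold change against a group whose arrays all lay at or below it was given as a lower bound, set against that yardstick.

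Each comparison was fitted with limma 3.58.1 in R 4.3.3 (lmFit with 1 mean per strain over all 9 arrays, then eBayes). Adjusted p-values followed Benjamini and Hochberg over the 2937 S. pombe probe sets of each comparison, and a probe set was called at an adjusted p under 0.05. SD1 and SD2 were each compared with WT, and SD2 with SD1. Calls shared by the deletions were set beside 100 simulations of unchanged groups and beside the overlap of independent lists. Each simulation drew all 9 arrays as independent noise around the WT means, so both deletions were compared with the same simulated WT group.

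A total of 34 gene lists were written before the data were examined, and 32 had the 3 measured members needed for a test. They held 1028 distinct genes, of which 800 were measured. The lists covered the deleted genes, flocculins and related adhesins, regulators of flocculation and filamentous growth, cell separation genes, cell wall glucan synthesis, galactosylation of cell surface glycans, ribosomal proteins of the large and of the small subunit, ribosome biogenesis, RNA polymerases I and III, and translation factors. Others covered the core environmental stress response, oxidative stress, heat shock proteins, mating and pheromone response, meiosis and sporulation, nitrogen starvation and amino acid uptake, amino acid biosynthesis, iron acquisition, copper and zinc homeostasis, phosphate acquisition, thiamine synthesis, hexose transport and glucose repressed genes, glycolysis, respiration, the mitochondrial ribosome, sterol synthesis, histones, S phase transcription, the proteasome, Tf2 retrotransposons, selection and auxotrophy markers, and markers of P and M cells. Both deleted genes were kept out of the ribosomal protein lists. Lists were tested with limma's camera at its preset correlation of 0.01, on the brightest probe set of each gene, with Benjamini-Hochberg adjustment over the 96 tests together. Members past the gene test were counted after adjustment over all probe sets and over the list alone.

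Genes were named by a rule fixed before the data were examined. It took the 12 largest rises and 12 largest falls of each deletion against WT and the 8 of each between the deletions, among calls in which the 3 arrays of one strain all lay above the 3 of the other. It added the deleted genes, the adhesins, the regulators, and up to 4 called members of each other list, or 2 members as values where none was called. Such a separation of 3 against 3 arrays arises by chance in 10% of unchanged genes.

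The strains shared replicate numbers, so deviations of same-numbered arrays from their strain means were correlated across S. pombe probe sets. The correlations were 0.28 to 0.85 between SD1 and WT and 0.13 to 0.87 between SD2 and SD1, above the 0.1 set in advance. Between SD2 and WT they ran from -0.10 to 0.79. By that rule the numbers paired the arrays in the first pair of comparisons. Between SD2 and WT the arrays numbered 1 and 3 passed it (0.79 and 0.33) and those numbered 2 did not. Same-numbered arrays of SD2 and WT shared equal values all the same. The main fit was set in advance without the number, and fits with it as a block are given as alternatives. Whether shared processing or a shared day of culture or hybridisation paired the arrays was not tested.

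Alternatives were the replicate number as a block, each array centred on its S. pombe median, quantile normalization over the S. pombe probe sets, dim probe sets left out, all probe sets tested together, 1 probe set per gene, an intensity trend with a robust prior, array weights, only the strains compared, a 2-fold minimum, an adjusted p under 0.01, and each array left out in turn. Lists were also tested with an estimated correlation and with fry. Fits on the 6 arrays numbered 2 and 3, with and without the block, were chosen after seeing the data. The pipeline was tested on simulated data, with 200 of 2937 probe sets changed. These data were independent noise around the WT means, with the fitted spread of each probe set. They held no shared deviations of same-numbered arrays or of related genes, so recovery and false calls may differ in the real arrays. At a 2-fold change, 88% of 50 probe sets were recovered in SD1 against WT, 94% in SD2 against WT and 92% in SD2 against SD1, with 6, 5 and 10 false calls. The S. cerevisiae and unnamed probe sets were left out of the tests because the first do not match the sample and the second could not be named here. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.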

Results

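Expression was measured in 3 strains of fission yeast, with 3 arrays each. WT was SPQ-01, SD1 lacked rpl32-1 and SD2 lacked rpl32-2, the paralogous genes for ribosomal protein L32 of the large ribosomal subunit. The series concerns cells that flocculate without mating. The median S. pombe value was 10.12 ± 0.068 (SD, n = 3) in WT, 10.07 ± 0.061 in SD1 and 10.11 ± 0.059 in SD2 on the log2 scale. The 3' minus 5' signal of 18S rRNA was -1.17 ± 0.32 in WT, -0.37 ± 0.055 in SD1 and -0.43 ± 0.13 in SD2, and that of 28S rRNA was -0.23 ± 0.21, 0.38 ± 0.23 and 0.26 ± 0.12 (log2, SD, n = 3). The same measure on ACT1 was 0.30 ± 0.083, 0.30 ± 0.032 and 0.33 ± 0.050.

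The deleted genes matched the labels in every array. The value of rpl3201 was 14.13 ± 0.29 in WT and 14.85 ± 0.32 in SD2, and it fell to 5.04 ± 0.94 in SD1, near the background of 5.17. The value of rpl3202 was 14.24 ± 0.13 in WT and 14.28 ± 0.18 in SD1, and it fell to 8.01 ± 0.83 in SD2, a mean still above that background. In log2 terms rpl3201 fell by 9.09 ± 0.41 (SE) in SD1 and rpl3202 fell by 6.23 ± 0.34 in SD2. The remaining paralog did not pass the test in either deletion, at 0.72 ± 0.41 for rpl3201 in SD2 (adjusted p = 0.22) and 0.04 ± 0.34 for rpl3202 in SD1 (adjusted p = 0.936). Both lay near the highest value of each array (14.43 to 15.12), which limits the rise that could be measured.

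**Figure D1:**
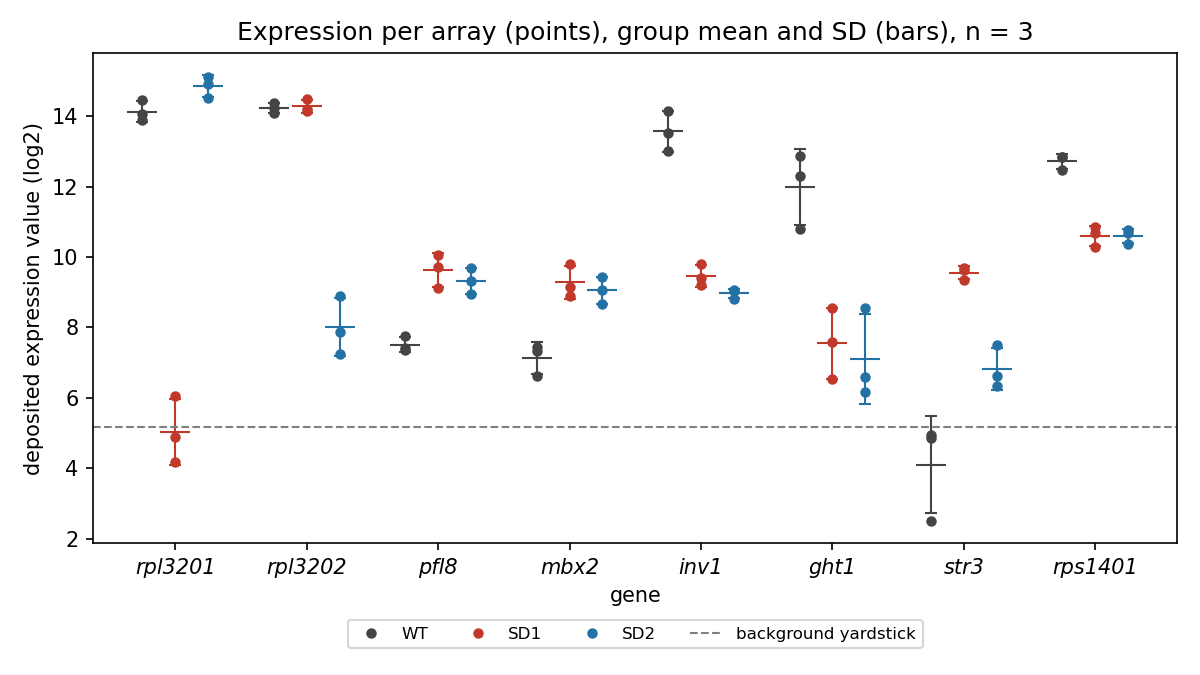
Deposited log2 expression of 8 genes in each array (points), with the mean and SD of the 3 arrays of each strain (bars) and the background yardstick of 5.17 (dashed line). rpl3201 is low only in the SD1 arrays and rpl3202 only in the SD2 arrays, among the strains plotted.

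SD1 was compared with WT to find the transcripts that changed with the loss of rpl32-1. Of the 44 measured ribosome biogenesis genes 41 rose and 0 fell, among them the nucleolar protein gene gar2 (4.55-fold, log2 2.18 ± 0.14 SE, n = 3 each), the large-subunit assembly gene mak16 (4.77-fold) and the RNA helicase gene dbp3 (4.45-fold). Of the 32 hexose transport and glucose repressed genes 24 fell and 2 rose. The invertase gene inv1 was 17.1-fold lower (log2 -4.10 ± 0.27), the hexose transporter gene ght1 21.7-fold lower (-4.44 ± 0.77) and the galactose pathway gene gal10 15.4-fold lower (-3.94 ± 0.47). Among the named S. pombe probe sets the largest rise was that of str3, a transporter gene of the iron acquisition list. It was at background in WT and at least 20.7-fold higher in SD1 (limma adjusted p = 0.000244).

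In all, 573 of 2937 S. pombe probe sets rose and 696 fell, 158 and 85 of them by at least 2-fold. With the replicate block 787 rose and 969 fell. Other large rises were those of the iron uptake genes fip1 (8.08-fold) and fio1 (6.09-fold), and of ani1, sda1, dbp2, srx1 and dea2 (log2 2.12 to 2.58). Other large falls were those of the copper amine oxidase gene cao2 (-3.60), the transporter genes ght4 (-3.02) and ght3 (-2.69), mug14 (-3.01), the galactose genes gal7 (-2.80) and gal1 (-2.77), gld1 (-2.62), a glycerol dehydrogenase gene, and gmh1 (-2.52), a galactosyltransferase gene.

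Only 3 of the 11 matched flocculin and adhesin genes had a named probe set. Of these, pfl8 rose 4.34-fold (log2 2.12 ± 0.26), mam3 fell 1.5-fold (-0.58 ± 0.19, adjusted p = 0.0322), and map4 was at -0.23 ± 0.094 (adjusted p = 0.0826). The call on mam3 was lost without WT array 2, WT array 3 or SD1 array 1. Over all arrays left out in turn its value ran from -0.71 to -0.38. Counted over the list alone 1 rose and 2 fell, and with the replicate block map4 passed at an adjusted p of 0.0388 (0.0101 to 0.251 over the alternatives). The list's median was -0.23, its mean was 0.44, and camera's direction was up without passing (adjusted p = 0.973). Of the 19 measured regulators 2 rose and 7 fell, with 2 and 7 adjusted over the list alone. The flocculin activator gene mbx2 rose 4.46-fold (log2 2.16 ± 0.30) and mbx1 rose 1.47-fold, while yox1 (-1.25), ldb1 (-0.78), sre2 (-0.74), sep1 (-0.65), med13 (-0.59), adn2 (-0.57) and tup11 (-0.33) fell. The calls on med13 and tup11 were lost without 1 of 4 and 1 of 7 arrays respectively, at adjusted p-values up to 0.0995 and 0.229 over the alternatives. The other 10 regulators lay between -0.36 and 0.17. With the block 2 regulators rose and 10 fell, the 3 added being ssn6 (-0.36), fkh2 (-0.35) and tup12 (-0.21). The regulators as a list were at an adjusted p of 0.215.

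The ribosome biogenesis list had a median log2 change of 1.43, with 1.39, 1.71 and 1.29 within arrays numbered 1, 2 and 3, and 41 genes rose adjusted over the list alone. Camera called it higher (adjusted p = 1.62e-21), and that call was lost at adjusted p = 0.573 with an estimated correlation. With that correlation 0 lists passed in any comparison and 0.573 was the lowest adjusted p, so such a loss does not tell lists apart. The estimates themselves differed among the called lists. They were 0.035 for amino acid biosynthesis, 0.63 for ribosome biogenesis, 0.76 for the large subunit and 0.80 for the proteasome, beside the preset 0.01. Where they were high, camera's p-values at the preset may be far too small. Fry kept the ribosome biogenesis call (0.00115) and those on RNA polymerases I and III (0.00115), translation factors (0.00977) and glucose repressed genes (0.0022). It also kept amino acid biosynthesis (0.0022), iron acquisition (0.0295) and M cell markers (0.0022), and lost 3 camera calls. The RNA polymerase I and III genes moved alike, with 20 of 24 higher and 0 lower (20 and 0 adjusted over the list alone, and 1 lower with the block), including the polymerase I genes rpa34 (1.73), rpa12 (1.66) and rpa49 (1.59) and its factor gene rrn3 (1.53). Their median was 0.93 (0.93, 1.00 and 0.91 within the numbers), called at adjusted p = 9.15e-10 and lost at adjusted p = 0.573 with an estimated correlation. Of 23 translation factor genes 15 rose and 1 fell (17 and 1 adjusted over the list alone), led by erf1 (1.02), tif225 (0.89), tif11 (0.88) and tif6 (0.77). Their median was 0.38 (0.32, 0.45 and 0.32), called at adjusted p = 3.53e-05 and lost at adjusted p = 0.734 with an estimated correlation. These genes were higher in the strain with the higher 18S rRNA 3' minus 5' signal, -0.37 in SD1 beside -1.17 in WT.

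Ribosomal protein genes moved little. In the large subunit 10 of 71 genes rose and 3 fell (6 and 3 adjusted over the list alone), and the median was 0.13 (0.09, 0.17 and 0.11 within the numbers). The list was called higher at adjusted p = 0.00175 and lost at adjusted p = 0.89 with an estimated correlation and at 0.227 with fry, and with the replicate block 40 of its genes rose. Its largest changes included rpl3402 (1.20) and rpl1603 (-0.49). In the small subunit 2 of 45 genes rose and 2 fell (1 and 1 adjusted over the list alone), with rps1401 4.33-fold lower (-2.11 ± 0.17) and rps2802 higher (0.52). That list was at an adjusted p of 0.1, and with the replicate block 13 genes rose and 2 fell and the list passed at 0.00328 (0.00328 to 0.934 over the alternatives).

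The hexose transport and glucose repressed list had a median of -0.81 (-0.65, -0.97 and -0.63 within the numbers), and 2 rose and 25 fell adjusted over the list alone. It was called lower at adjusted p = 1.38e-05 and lost at adjusted p = 0.573 with an estimated correlation. In respiration 14 of 41 genes fell and 1 rose (14 and 1 adjusted over the list alone), among them the citric acid cycle genes idh1 (-1.29), idh2 (-1.08) and cit1 (-1.02). Its median was -0.17 (-0.11, -0.32 and -0.14), called at adjusted p = 0.0143 and lost at adjusted p = 0.89 with an estimated correlation and at 0.132 with fry. It was also lost without WT array 1 or SD1 array 2. In amino acid biosynthesis 21 of 47 genes rose and 6 fell (23 and 7 adjusted over the list alone, and 10 lower with the block), including the arginine genes arg5 (1.18), arg4 (1.09) and arg1 (0.95). The median was 0.20 (0.26, 0.27 and 0.22), called at adjusted p = 0.0106 and lost at adjusted p = 0.573 with an estimated correlation.

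Of 16 iron acquisition genes 8 rose and 1 fell (9 and 1 adjusted over the list alone), led by str3, fip1, fio1 and the ferric reductase gene frp1 (2.10). The median was 0.84 (0.60, 1.34 and 0.56), called at adjusted p = 0.0159 and lost at adjusted p = 0.734 with an estimated correlation. The call was also lost without SD1 array 2. Of 8 M cell markers 6 fell (6 adjusted over the list alone), among them the M-factor transporter gene mam1 (-1.66) and the M-factor gene mfm1 (-1.27). The median was -0.76 (-0.99, -0.64 and -1.07), called at adjusted p = 0.0168 and lost at adjusted p = 0.573 with an estimated correlation, and lost too without WT array 1. Of 28 proteasome genes 5 fell and 0 rose (1 and 0 adjusted over the list alone), rpn2 the most (-0.62), and with the replicate block 15 fell. The median was -0.16 (-0.13, -0.25 and -0.17), called at adjusted p = 0.0412 and lost at adjusted p = 0.893 with an estimated correlation, at 0.208 with fry, with each array centred on its median, and without WT array 1, SD1 array 2 or SD1 array 3.

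SD2 was compared with WT to find the transcripts that changed with the loss of rpl32-2. Of the 44 ribosome biogenesis genes 41 rose and 0 fell, including gar2 (3.29-fold, log2 1.72 ± 0.14 SE, n = 3 each), dbp2 (3.19-fold) and mak16 (3.14-fold). Of the 32 hexose transport and glucose repressed genes 22 fell and 2 rose, with ght1 29.8-fold lower (-4.90 ± 0.77), inv1 24.3-fold lower (-4.60 ± 0.27) and ght3 10.7-fold lower (-3.42 ± 0.26). The adhesin gene pfl8 rose 3.52-fold (1.82 ± 0.26) and its regulator gene mbx2 rose 3.79-fold (1.92 ± 0.30).

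In all, 518 probe sets rose and 419 fell, 97 and 44 of them by at least 2-fold (764 and 694 with the replicate block at any fold). The number that fell was 261 without WT array 2, 261 without SD2 array 2 and 270 without SD2 array 3. Among the largest rises by fitted value, str3 was at least 3.11-fold higher and mug95 at least 1.7-fold higher, both at background in WT. By its bound alone mug95 would not rank there. Also among them were ani1 (2.17), mug115 (1.87) and dea2 (1.68). The uracil-regulated genes urg1 (2.05) and urg2 (1.66) rose as well. Among the largest falls were gal10 (-3.87), mug14 (-3.34), gld1 (-3.30), ght4 (-2.97), gal7 (-2.87), gal1 (-2.85), cao2 (-2.25) and rps1401 (-2.12 ± 0.17).

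Of the 3 measured adhesin genes mam3 fell 1.58-fold (-0.66 ± 0.19, adjusted p = 0.0257), and map4 was at -0.20 ± 0.094 (adjusted p = 0.143). The call on mam3 was lost without WT array 2 or 3 or SD2 array 1 or 3. Its value ran from -0.78 to -0.52 over all arrays left out in turn. Counted over the list alone 1 rose and 1 fell, with a list median of -0.20, a mean of 0.32 and camera's direction down (adjusted p = 0.876). Of the 19 regulators 1 rose (mbx2) and 4 fell, with 1 and 4 adjusted over the list alone and 2 and 6 with the replicate block. The 4 that fell without the block were yox1 (-0.96), ldb1 (-0.84), sre2 (-0.60) and sep1 (-0.50). The call on yox1 was lost without WT array 2 or SD2 array 2, and that on sre2 without 1 of 5 arrays, at adjusted p-values up to 0.0854 and 0.115 over the alternatives. The other 14 lay between -0.44 and 0.28, and the list was at an adjusted p of 0.159.

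The ribosome biogenesis median was 1.04 (0.93, 1.41 and 0.88 within arrays numbered 1, 2 and 3), with 41 higher adjusted over the list alone, called at adjusted p = 1e-18 and lost at adjusted p = 0.573 with an estimated correlation. Fry kept this call (adjusted p = 0.0022) and those on RNA polymerases I and III (0.00115) and translation factors (0.0193). It also kept glucose repressed genes (0.00234) and amino acid biosynthesis (0.0022), and lost 3 camera calls. Of 24 RNA polymerase I and III genes 19 rose and 0 fell (20 and 0 adjusted over the list alone), with a median of 0.79 (0.77, 0.92 and 0.78), led by rpa34 (1.43) and rrn3 (1.32). The call at adjusted p = 9.15e-10 was lost at adjusted p = 0.573 with an estimated correlation. Of 23 translation factor genes 12 rose and 0 fell (16 and 1 adjusted over the list alone), with a median of 0.29 (0.24, 0.39 and 0.23). The call at adjusted p = 0.000237 was lost at adjusted p = 0.753 with an estimated correlation. Beside these rises the 18S rRNA 3' minus 5' signal was -0.43 in SD2 and -1.17 in WT. In the large ribosomal subunit 6 of 71 genes rose and 3 fell (3 and 2 adjusted over the list alone, and 27 and 3 with the replicate block), with a median of 0.10 (0.06, 0.15 and 0.08). Its call at adjusted p = 0.029 was lost at adjusted p = 0.934 with an estimated correlation, at 0.344 with fry, with each array centred on its median, and without WT array 2, WT array 3 or SD2 array 1. Its list mean ran from 0.07 to 0.18 over all arrays left out in turn. In the small subunit 1 of 45 genes rose and 1 fell (0 and 1 adjusted over the list alone), at an adjusted p of 0.397.

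The hexose transport and glucose repressed median was -0.62 (-0.46, -0.94 and -0.44), with 3 higher and 23 lower adjusted over the list alone, called at adjusted p = 1.36e-07 and lost at adjusted p = 0.573 with an estimated correlation. In respiration 9 of 41 genes fell and 0 rose (9 and 0 adjusted over the list alone), including idh1 (-0.98) and cit1 (-0.80). The median was -0.14 (-0.06, -0.33 and -0.05), called at adjusted p = 0.00503 and lost at adjusted p = 0.89 with an estimated correlation, at 0.246 with fry, and lost too without WT array 1 or SD2 array 2. Its list mean ran from -0.28 to -0.13 over all arrays left out in turn. In amino acid biosynthesis 19 of 47 genes rose and 3 fell (22 and 3 adjusted over the list alone), with arg4 at 1.10 and arg5 at 1.00. The median was 0.25 (0.26, 0.22 and 0.23), called at adjusted p = 0.00849 and lost at adjusted p = 0.573 with an estimated correlation. Of 24 S phase transcription genes 6 fell and 1 rose (7 and 1 adjusted over the list alone), including nrm1 (-0.89), a repressor of that programme. The median was -0.34 (-0.16, -0.79 and -0.15), called at adjusted p = 0.0159 and lost at adjusted p = 0.734 with an estimated correlation, at 0.0687 with fry, and lost without SD2 array 2, with list means from -0.48 to -0.24 over the arrays left out. Of 16 iron acquisition genes 2 rose and 1 fell (2 and 1 adjusted over the list alone), and of 8 M cell markers 3 fell (3 adjusted over the list alone), neither list passing (adjusted p = 0.654 and 0.0707).

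**Figure D2:**
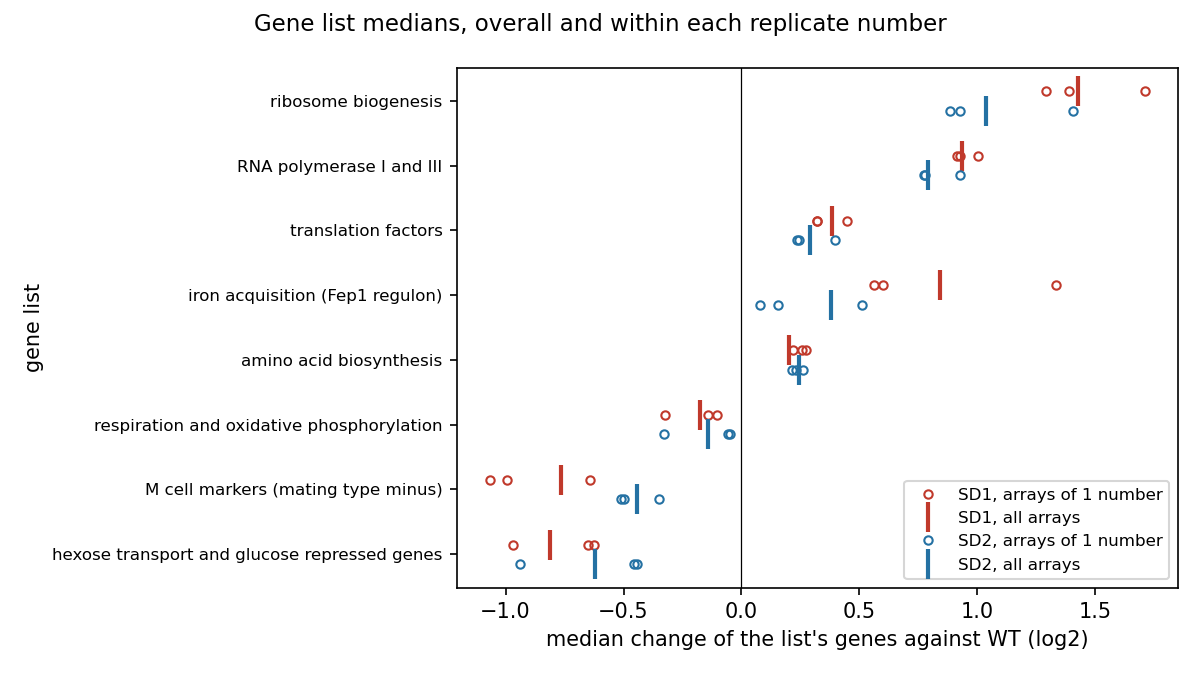
Median log2 change against WT of 8 gene lists in SD1 and SD2, over all arrays (vertical ticks) and within the arrays of each replicate number (circles). The ribosome biogenesis medians lie between 0.88 and 1.71 and those of the glucose repressed genes between -0.97 and -0.44.

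SD2 was compared with SD1 to test whether loss of the paralogs had different effects. Apart from the deleted genes, 2 genes passed the test, and both were lower in SD2. The tlh2 gene, which encodes a telomere-linked helicase, was lower in SD2 by -2.16 ± 0.22 in log2 terms (adjusted p = 0.00469) in 1 probe set and by -1.79 ± 0.15 in another. The iron transport gene fip1 was lower by -1.98 ± 0.27 (adjusted p = 0.0327, n = 3 each). Every adhesin and regulator measured failed to pass in this comparison, with adn2 the farthest from 0 among the regulators (0.39 ± 0.11, adjusted p = 0.264) and pfl8 at -0.30 ± 0.26.

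In all, 1 probe set rose and 4 fell, and 334 had an unadjusted p under 0.05. With the replicate block 16 rose and 9 fell, 4 of the 5 calls among them. The call on fip1 was the one lost, at an adjusted p of 0.0527 (0.000303 to 0.637 over the alternatives), with its value of -1.98 unaltered by the block. It was also lost without any 1 of 5 arrays, SD1 array 1, 2 or 3 or SD2 array 1 or 3. Over all arrays left out in turn its value ran from -2.18 to -1.83. Without WT array 2, which enters only the shared estimate of the spread, 3 probe sets rose and 7 fell.

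Ribosome biogenesis genes were lower in SD2 than in SD1 by a median of -0.39 (-0.47, -0.25 and -0.42 within the numbers), with 0 of 44 passing singly, 3 with the replicate block and 20 lower adjusted over the list alone. Camera called the list lower (adjusted p = 1e-26), lost at adjusted p = 0.573 with an estimated correlation. The RNA polymerase I and III list was lower by -0.17 (-0.17, -0.15 and -0.15), with 0 of 24 passing and 1 with the block, called at adjusted p = 1.09e-06 and lost at adjusted p = 0.573 with an estimated correlation. The iron acquisition list was lower by -0.64 (-0.34, -1.12 and -0.39), with 1 of 16 passing (0 with the block) and 6 lower adjusted over the list alone, called at adjusted p = 8.22e-10 and lost at adjusted p = 0.573 with an estimated correlation. M cell markers were higher by 0.52 (0.56, 0.41 and 0.58), with 0 of 8 passing, 3 with the block and 3 higher adjusted over the list alone, called at adjusted p = 0.00374 and lost at adjusted p = 0.573 with an estimated correlation. With the block mfm1 (0.60) and mfm2 (0.77) passed, at 0.0237 and 0.0307 (up to 0.712 and 0.895 over the alternatives).

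Smaller shifts were called in translation factors (median -0.06, adjusted p = 0.00374), in ribosomal proteins of the large (-0.027, 0.00374) and small subunit (-0.023, 0.0303), and in copper and zinc homeostasis (-0.20, 0.00617), with 0 members passing in each. These 4 smaller shifts were lost at adjusted p = 0.79, 0.893, 0.918 and 0.573 with an estimated correlation, which was 0.55, 0.76, 0.75 and 0.15. Within arrays numbered 1, 2 and 3 the medians were -0.077, -0.029 and -0.085 for translation factors and -0.028, -0.014 and -0.038 for the large subunit. They were -0.015, -0.016 and -0.032 for the small subunit and -0.034, -0.33 and -0.042 for the copper and zinc list. Of the 8 lists called between the deletions fry called only the M cell markers (adjusted p = 0.0319). Each of the 4 was lost without at least 1 array: translation factors without SD1 array 1 or SD2 array 3, both subunits without SD1 array 1 or SD2 array 2 or 3, and the copper list without SD1 array 2. List means over the arrays left out were -0.10 to -0.01, -0.07 to 0.02 for each subunit, and -0.28 to -0.10. Both subunits were also lost after quantile normalization, and the proteasome list (median 0.10, adjusted p = 0.0877) passed with the block, at 0.00622 (0.00014 to 0.93 over the alternatives). The hexose transport and glucose repressed list had a median of 0.06, a mean of -0.01 and camera's direction down, at an adjusted p of 0.838. It was 1 of 12 lists whose median, mean and test differed in sign in this comparison, 0 of them called by camera.

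The changes in SD1 and SD2 were compared with each other because both rested on the same WT arrays. The medians of the ribosome biogenesis and glucose repressed genes each had the same sign in both. Of the probe sets, 478 rose in both deletions and 406 fell in both, and 0 were called in opposite directions. Independent lists of these sizes would share 101 and 99.3. Unchanged groups compared with 1 simulated WT group shared 0 and 0. Such groups give almost no calls to share, so these counts do not measure the sharing due to common controls. Of the 1320 probe sets called in either, the deleted genes aside, 1308 had the same sign in both, and 1092 changed more in SD1. The median absolute log2 change of these was 0.55 in SD1 and 0.43 in SD2. They were selected by calls, of which SD1 had more (1269 beside 937), and this by itself favours larger changes in SD1.

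The covariance of the log2 fold changes across probe sets was 0.281, beside a simulated mean of 0.0133 (0.00964 to 0.0327 over 100 simulations), and the difference was 0.268. The simulated noise was independent between probe sets and arrays, unlike the deviations of the real arrays, so its range may be too narrow. The correlation was 0.877 across probe sets, which are not independent replicates, and 0.942 without the deleted genes, beside 0.491 in the simulations. The number that fell in both was 253 without WT array 2, 252 without SD2 array 2 and 263 without SD2 array 3.

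**Figure D3:**
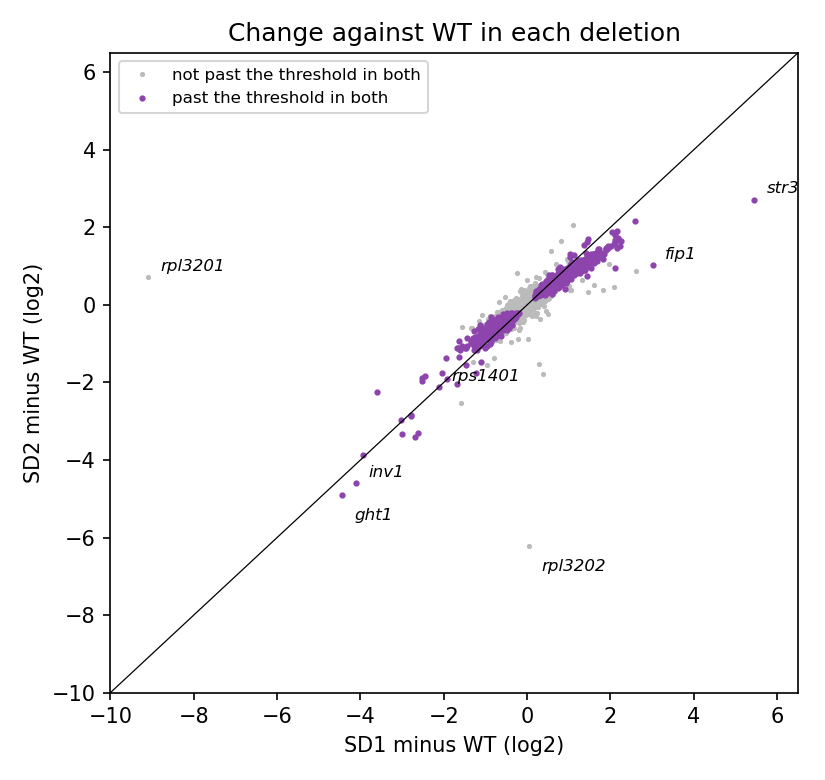
Log2 change against WT of every S. pombe probe set in SD1 and SD2, with the line of equal change. Probe sets past the threshold in both were 478 higher and 406 lower, and the deleted genes rpl3201 and rpl3202 lie far from the line.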

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

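The splits of the arrays, the covariance between differences that share no array and the chromosome medians were planned before their results were seen, and every other test in this part was chosen afterwards.

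The gene tlh2 was lower in SD2 than in SD1, by -2.16 and -1.79 in 2 of its 4 probe sets, while WT lay near SD1. With any 1 SD1 or SD2 array left out, the probe set at -1.79 stayed at -1.69 ± 0.16 (SE) or beyond, so no 1 array carried that difference. It was chosen as a call, and its arrays lay apart too. The naming rule passed it over only because it took 1 probe set per gene, so this is no independent test of 1 deviating array. At -2.16 the gap of -1.45 between the strains' arrays was a condition of the naming rule and decides nothing. Loss of the chromosome end as far as the nearest measured named gene, gal1, was not decided. The gal1 gene differed by -0.073 ± 0.25 (SE). It was, however, among the largest falls of both deletions against WT, and whether it could fall further above background was not tested. The 30 annotated genes between them were not tested either. Fewer tlh copies at chromosome ends may still account for it and cannot be told apart, because the brightest probe set that did not differ (0.017) lay only 0.52 above background in SD1. A lower transcript level in SD2, the biological explanation, stayed open, and on the arrays numbered 2 and 3 alone tlh2 lost its call at 1 probe set, where the value was -2.34, and not at the other (-1.89).

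The shared response came with several technical explanations. Chance values of the shared WT arrays were ruled out as its whole cause, since the lowest covariance between differences that share no array was 0.221 and the highest 0.337. A part may still come from the shared controls. It was 0.0133 in simulations, whose independent noise may make it too small. A single processing set was ruled out as the sole source of the ribosome biogenesis and glucose repressed shifts only. The ribosome biogenesis median was at least 0.883 within each number and deletion and the glucose repressed median at most -0.443. For the rest of the shared response a processing set was not ruled out. The covariance of SD1 and SD2 differences that share a WT array was 0.465 within arrays numbered 2. It was 0.226 and 0.222 within those numbered 1 and 3. A difference in culture stage at harvest could account for both groups and cannot be told apart, since the SD2 to SD1 ratio of the medians was 0.727 for ribosome biogenesis and 0.768 for glucose repressed genes (SD over the numbers 0.0847 and 0.153) and the labels give 1 OD600 for all strains. Loss of either L32 gene stayed open as the biological explanation. Any other difference from WT that both deletion strains share cannot be told apart from it. One such difference was a reporter probe set at least 6.88 higher in SD1 and 6.73 higher in SD2.

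The gene rps1401, near rpl3202 on its chromosome in assembly ASM294v3, was lower in both deletions. Reach of the rpl3202 deletion was ruled out as the whole cause, since rps1401 was lower in SD1 too (-2.11 ± 0.17), where rpl3202 is intact. A general fall of small-subunit genes was ruled out, since the lower of the list medians without it was 0.0492. A strain difference that was there before the deletions may explain it and cannot be told apart from an effect of both, because SD2 and SD1 differed by -0.0024 ± 0.17.

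Other splits of the same arrays were tried. With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The real split called 1269 probe sets in SD1 against WT, 937 in SD2 against WT and 5 in SD2 against SD1, and the highest of the others called 0 in each, so 1, 1 and 1 of 10 splits called as many. For gene lists the real splits called 10, 8 and 8 and the highest others 15, 16 and 13, and 6, 9 and 7 of 10 splits called as many. Of the 3 other splits that part all pairs of numbers, the highest called 12 lists for SD1 and WT, 11 for SD2 and WT and 8 for SD2 and SD1. Every other split divided the strains unevenly, so part of the strain difference stayed in it. That difference also widened the spread within its groups. Neither the 0 probe sets nor the lists called in such splits therefore measure chance. The list calls at the preset correlation were matched in number by these mixed groups of arrays, so their number alone does not set the strains apart. Whether this is tied to their loss with an estimated correlation (0 lists in each comparison) was not tested. Of 100 splits of the 9 arrays, drawn from 840, 2 shared as many calls between the deletions, the real one (884) and 1 that kept WT as the control and mixed the deletions (908). The 3 splits that kept WT shared at least 836, so the count shows that the WT arrays stood apart from the deletion arrays. It does not test SD1 and SD2 as groups, the splits ignored the replicate numbers, and a difference between strains or cultures stays possible. The splits drawn that did not keep WT shared at most 240.

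No chromosome stood apart in either deletion. The chromosome median farthest from that of all genes lay -0.00868 from it, far from an extra copy of a chromosome.

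The remaining results are values without an explanation. The fip1 gene was lower in SD2 than in SD1 by -1.98. Between the deletions, SD2 minus SD1 list medians were -0.386 for ribosome biogenesis, -0.168 for RNA polymerases I and III, -0.0592 for translation factors, -0.0267 and -0.0228 for ribosomal proteins of the large and small subunit, -0.635 for iron acquisition, -0.198 for copper and zinc homeostasis and 0.518 for M cell markers. In data outside the comparisons, 1 of 47 reporter probe sets had all arrays of each deletion above those of WT and a mean over 2-fold higher. It differed from WT by 9.22 in SD1 and 9.07 in SD2, without a test. Its WT arrays all lay below background, and against the yardstick it was at least 6.88 and 6.73 higher. Another probe set of the same reporter entry was at 8.77 in WT, 8.89 in SD1 and 9.01 in SD2. Among the 5177 unnamed probe sets 950 were called in SD1 against WT and 728 in SD2 against WT.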

How the results depend on the processing

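The alternatives named as only the 6 arrays numbered 2 and 3 were chosen after seeing the data, and the others before. Arrays have no depth, and a WT value at background limited the folds of str3 and mug95 to lower bounds. With the replicate block 694 probe sets fell in SD2 against WT, 669 fell in both deletions, and 16 rose and 9 fell in SD2 against SD1. In SD2 against WT the block gave higher and lower counts of 27 and 3 in the large subunit, 6 and 1 in the small subunit, 14 and 5 in oxidative stress, 19 and 5 in meiosis, 6 and 10 in mating and 7 and 10 in heat shock. They were 7 and 8 in cell wall glucan, 0 and 5 in cell separation, 7 and 13 in the mitochondrial ribosome, 0 and 15 in respiration, 9 and 7 in sterols, 4 and 2 in iron acquisition and 0 and 5 in the proteasome. Flocculation regulators counted 2 and 6, translation factors 18 and 1, glycolysis 2 and 6 and histones 3 and 2. Selection markers counted 5 and 1, thiamine genes 4 and 1 and phosphate genes 1 and 0. All 10928 probe sets tested together, which by construction tests more, gave 1002 higher and 1056 lower in SD1 and 856 and 642 in SD2. Array weights gave 1069 lower in SD1, 886 higher and 762 lower in SD2, and 334 higher and 154 lower in SD2 against SD1. Their estimation did not converge, and 1 array held 92.0% of the WT weight, 73.2% of SD1's and 78.0% of SD2's. A 2-fold minimum, which can only lower a count, gave 158 and 85 in SD1, 97 and 44 in SD2, and 94 and 38 in both. An adjusted p under 0.01 gave 412 lower in SD1 and 318 and 185 in SD2. With an estimated correlation 0, 0 and 0 lists passed by camera, and fry called 1 in SD2 against SD1. On the arrays numbered 2 and 3, 654 rose and 841 fell in SD1, 613 and 516 in SD2, and 2 and 2 in SD2 against SD1. With the block on them 295 rose and 206 fell in SD2 against WT, 2 fell in SD2 against SD1, and 284 rose and 193 fell in both. For the block, the weights, fry and the fits on arrays 2 and 3 the cause was not tested. With each array left out, 455 to 572 rose and 497 to 751 fell in SD1, 383 to 520 and 261 to 486 in SD2, 1 to 3 and 3 to 7 in SD2 against SD1, and 366 to 475 and 252 to 463 in both. The covariance ran from 0.220 to 0.327, and lists called from 7 to 13, 6 to 11 and 6 to 11. In SD2 against WT the M cell list, at an adjusted p of 0.0707, passed with the block at 0.0469 (0.0295 to 0.711 over the alternatives).

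Of the gene values under the alternatives 72 of 7281 changed direction, 49 of them with an array left out, and of the list tests 77 of 1536, 46 of them with an array left out. In these, 0 passed the limma or camera threshold in either setting, and the cause was not tested. Values are log2 changes, with list means for lists, where camera or fry gave the direction. With the replicate block these were in SD1 against WT adhesins 0.44, heat shock -0.17 and sterols -0.020. With arrays centred these were in SD1 against WT cbf11 0.024, srb11 0.023, cbf12 0.013 and adhesins 0.48, and in SD2 against SD1 map4 -0.0076, tlh2 -0.019 and core stress -0.034. After quantile normalization these were in SD1 against WT cbf11 0.040, srb11 0.027, cbf12 0.0051, adhesins 0.48 and meiosis and sporulation -0.0012, and in SD2 against SD1 map4 -0.013, tlh2 -0.14, tlh2 0, flocculation regulators -0.015, core stress -0.024, heat shock 0.0086 and glucose repressed genes -0.053. With array weights these were in SD1 against WT cbf11 0.046 and cbf12 0.086, in SD2 against WT srb11 -0.00019 and csk1 -0.0056, and in SD2 against SD1 map4 -0.022, srb10 0.032, tup12 0.026 and tlh2 -0.017. With fry these were in SD1 against WT cell wall glucan 0.0078, galactosylation -0.23 and histones -0.13, in SD2 against WT adhesins 0.32 and histones -0.094, and in SD2 against SD1 cell separation 0.0027, cell wall glucan -0.0014, core stress 0.0021, heat shock 0.016, amino acid biosynthesis 0.0052, thiamine synthesis 0.0087, glucose repressed genes -0.013, histones 0.039, S phase 0.069, selection markers -0.014 and P cell markers 0.026. On arrays 2 and 3 these were in SD1 against WT srb11 0.0016, adhesins 0.43, heat shock -0.15 and sterols -0.022, and in SD2 against SD1 lkh1 0.0072 and P cell markers 0.056. On those with the block these were in SD1 against WT srb11 0.0016, and in SD2 against SD1 lkh1 0.0072.

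With an array left out, these results changed direction at least once, and their lowest and highest values are given, tlh2 being the probe sets of it that did not pass. In SD1 against WT they were rpl3202 -0.061 to 0.11, lkh1 -0.034 to 0.32, adhesins 0.30 to 0.52, cell wall glucan -0.030 to 0.041, heat shock -0.20 to -0.13, sterols -0.082 to 0.041, histones -0.20 to -0.078, cbf11 -0.12 to 0.069 and cbf12 -0.11 to 0.065. Further values in SD1 against WT were adn3 -0.21 to 0.023 and srb11 -0.074 to 0.044. In SD2 against WT they were fkh2 -0.19 to 0.0023, cbf11 -0.025 to 0.16, lkh1 -0.10 to 0.33, heat shock -0.22 to -0.10, histones -0.20 to -0.0012, adn3 -0.22 to 0.011, small-subunit proteins -0.025 to 0.078, sterols 0.010 to 0.12 and csk1 -0.0032 to 0.26. In SD2 against SD1 they were cell separation -0.060 to 0.061, cbf12 -0.17 to 0.0049, tup12 -0.058 to 0.040, rpl4101 -0.062 to 0.22, csk1 -0.075 to 0.19, tlh2 -0.092 to 0.12, tlh2 -0.13 to 0.086, flocculation regulators -0.0028 to 0.086 and heat shock -0.045 to 0.069. Further values in SD2 against SD1 were histones -0.065 to 0.13, map4 -0.052 to 0.098, ldb1 -0.16 to 0.020, ssn6 -0.21 to 0.021, adn3 -0.11 to 0.085, core stress -0.053 to 0.062, glucose repressed genes -0.080 to 0.063, glycolysis 0.0030 to 0.094 and respiration -0.0077 to 0.16. Further values in SD2 against SD1 were mitochondrial ribosome 0.026 to 0.091, mam3 -0.28 to 0.062, mbx2 -0.43 to 0.023, tup11 -0.023 to 0.12, lkh1 -0.24 to 0.16, P cell markers -0.0096 to 0.068, ams2 -0.033 to 0.55, cnp1 -0.0028 to 0.27 and cig2 -0.030 to 0.52. Further values in SD2 against SD1 were proteasome 0.013 to 0.17, srb10 -0.29 to 0.016, adg1 -0.71 to 0.055, adg2 -0.44 to 0.013 and S phase -0.041 to 0.20.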

Other observations

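Further gene groups moved in parts in SD1 and SD2 against WT without their lists passing camera's test at the preset correlation, unless a value says otherwise. Core stress genes went both ways, with 8 of 41 higher and 17 lower in SD1 and 8 and 15 in SD2 (10 and 17, and 8 and 15, adjusted over the list alone). The stress gene tms1 fell by 2.45 in SD1 and by 1.83 in SD2, and lsd90 fell by 1.93 and 1.92. The genes tms1, gpd1, gut2, dak1, dak2 and ald1 were also written in the glucose repressed list, so the lists overlap. Of 21 oxidative stress genes 11 rose and 5 fell in SD1 and 5 rose and 4 fell in SD2 (12 and 5, and 8 and 5, adjusted over the list alone), with the sulfiredoxin gene srx1 higher by 2.12 in SD1. Of 29 heat shock and chaperone genes 4 rose and 7 fell in SD1 and 3 rose and 6 fell in SD2 (4 and 6, and 3 and 6, adjusted over the list alone). The Hsp70 gene ssa1 fell by 1.69 and 2.04, and that list had medians of 0.036 and 0.028, means of -0.17 and -0.15 and a test pointing down (adjusted p = 0.849 and 0.654).

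Of 39 mating and pheromone genes 14 fell in SD1 and 9 in SD2, with 3 higher in each (3 and 14, and 2 and 9, adjusted over the list alone; adjusted p = 0.0877 and 0.138). That list also holds the M and P cell markers. Its member ste7 fell by 1.12 and 1.48. Of 4 P cell markers only map2, the P-factor gene, rose, by 1.11 in SD1 and 0.96 in SD2 (1 and 0 adjusted over the list alone in each; adjusted p = 0.843 and 0.752), with list medians of -0.091 and 0.021 and means of 0.18 and 0.20. Of 65 meiosis and sporulation genes 11 rose and 7 fell in SD1 and 11 rose and 3 fell in SD2 (9 and 4, and 11 and 3, adjusted over the list alone; adjusted p = 0.672 and 0.124), with mde5 higher by 1.40 and 1.20. Of 24 nitrogen and uptake genes 7 rose in each deletion and 6 and 5 fell (8 and 6, and 8 and 5, adjusted over the list alone; adjusted p = 0.53 and 0.24), with the ammonium transporter gene amt1 higher by 1.44 and 1.61.

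Of 17 cell separation genes 0 rose and 3 and 2 fell in SD1 and SD2 (0 and 2, and 0 and 1, adjusted over the list alone; adjusted p = 0.222 and 0.133). Of 32 cell wall glucan genes 5 rose and 6 fell in SD1 and 4 rose and 2 fell in SD2 (5 and 5, and 2 and 2, adjusted over the list alone; adjusted p = 0.881 and 0.748), with the glucanase gene exg3 lower by -1.06 and -0.58 and the chitin synthase gene chs1 higher by 0.74 and 0.71. That list had medians of -0.030 and -0.010 and means of 0.0078 and 0.0064. Of 19 galactosylation genes 4 rose and 4 fell in SD1 and 3 rose and 5 fell in SD2 (4 and 4, and 4 and 6, adjusted over the list alone; adjusted p = 0.752 in both), with omh5 higher by 1.12 and 0.99. The largest changes of that list were the falls of gal10, by -3.94 and -3.87, a gene also counted with the glucose repressed genes. In SD1 the galactosylation list had a median of 0.11 and a mean of -0.23, and its test pointed up.

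Metabolic groups gave these counts of genes higher and lower in SD1 and then in SD2. Copper and zinc genes counted 7 and 1, then 4 and 0, of 13 (7 and 3, then 4 and 0, adjusted over the list alone; adjusted p = 0.0852 and 0.27), with the zinc-regulated gene adh4 higher by 1.38 and 1.09. Phosphate genes counted 1 and 0, then 0 and 0, of 3 (1 and 0, then 0 and 0 with limma, adjusted over the list alone; adjusted p = 0.577 and 0.656). Thiamine genes counted 4 and 1, then 3 and 0, of 12 (4 and 2, then 3 and 0, adjusted over the list alone; adjusted p = 0.4 and 0.367). Glycolysis counted 1 and 5, then 1 and 4, of 16 (1 and 5 in both adjusted over the list alone; adjusted p = 0.198 and 0.186), with ght5 lower by -0.81 and -0.68. Mitochondrial ribosome genes counted 5 and 14, then 5 and 6, of 48 (5 and 14, then 1 and 5, adjusted over the list alone; adjusted p = 0.147 and 0.215). Sterol genes counted 8 and 7, then 5 and 5, of 28 (8 and 7, then 6 and 5, adjusted over the list alone; adjusted p = 0.876 and 0.967). Histone genes counted 3 and 2, then 3 and 0, of 12 (3 and 2, then 3 and 1, adjusted over the list alone; adjusted p = 0.944 and 0.849). Selection markers counted 3 and 1 in both, of 10 (5 and 2, then 4 and 1, adjusted over the list alone; adjusted p = 0.358 and 0.372). In SD1 the S phase genes counted 2 and 9 of 24 (2 and 9 adjusted over the list alone; adjusted p = 0.0707), and in SD2 the proteasome genes counted 0 and 1 of 28 (0 and 0 adjusted over the list alone; adjusted p = 0.143). The counts in SD1 that moved by over 1.5 times with the replicate block became 2 and 7 for cell separation, 11 and 10 for cell wall glucan, 7 and 11 for heat shock, 6 and 17 for mating, 16 and 14 for meiosis, 6 and 2 for copper and zinc, 4 and 3 for thiamine, 2 and 9 for glycolysis, 3 and 5 for histones, 5 and 2 for selection markers and 1 and 1 for P cell markers. The Tf2 retrotransposon list had 0 measured members, and the list of deleted genes had 2 and was not tested.

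Among the 2601 S. cerevisiae probe sets limma called 1 in SD1 against WT, 0 in SD2 against WT and 0 in SD2 against SD1, and 132, 139 and 151 had an unadjusted p under 0.05. The largest fall among the 5177 unnamed probe sets was -5.12 ± 0.56 (SE, n = 3) in SD1, and the same probe set was at -3.37 ± 0.56 in SD2. The largest rise among them was 6.77 ± 1.15 in SD1, where WT array 2 was at 0.658, the lowest value on that array. Both were chosen after their values were seen.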
